A study of Rattus norvegicus with 12 samples.

How the data were processed

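Cultured rat oligodendrocyte precursor cells were exposed to tunicamycin at 0 or 5 µM for 2 or 8 h, and each of the 4 groups held 3 libraries. Per the labels, the cells had been isolated from adult spinal cord and used at low passage, and the 12 libraries came from 3 independent experiments with 4 samples each. Libraries were made, per the labels' protocols, from total RNA with a stranded kit after removal of ribosomal RNA and were sequenced on an Illumina NextSeq.

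The authors deposited 1 table of FPKM values (fragments scaled by gene length and by a size of the library) for 32402 Ensembl rat genes. Median-ratio factors of the 12 libraries ran from 0.996 to 1.01, although summed FPKM ran from 588250 to 764988. This goes with values that were already scaled between libraries by such factors, rather than by the fragments of each library alone. The submitters' processing notes name FastQC 0.10.1, TopHat2 2.0.4, Cufflinks 2.2.1, Cuffdiff 2.1.1, Cuffnorm without a version, and the build rn6. They give no role or order for these tools. How fragments were counted per gene is not given in the sources used here. No fragment counts were used, so no count model was run. Samples were grouped by the treatment and time in their titles, and each column of the table was matched to its sample by the treatment, time and replicate number in its name.

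The gene IDs could not be turned into names. The reference table given with the data holds 47357 genes, of which 0 carry an Ensembl ID, and 0 of its entries matched an ID of the deposited table in any column. The files do not pair the IDs with names. The gene lists fixed before the data were examined (unfolded protein response branches, lineage and myelin genes, markers of other cell types and others) therefore have no result here. The rule for named genes, fixed at the same time, took the 10 largest rises and falls among called genes whose 3 treated libraries all lay on 1 side of the 3 control libraries, and 5 each way for the other comparisons. It named only genes with a symbol, and a set of genes of interest whatever their values. None could be named, so genes are described as counts and ranges, and 2 IDs that rose and 2 listed lower were printed. These are the 2 largest rises at 8 h and the largest fall at 8 h among genes not listed at 0 in any library while at 10 FPKM or more in another, together with 1 gene listed at 0. This choice was made after the values were seen.

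Genes with a mean of at least 1 FPKM over the 12 libraries were tested, which left 12056. Values were transformed to log2(FPKM + 1), so all log2 fold changes are on this scale and understate the change of genes with low values. Group means were fitted to all 12 libraries with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend on mean expression. The fit had 8 residual degrees of freedom and 2.01 prior degrees of freedom. Adjusted p-values are limma's with Benjamini-Hochberg adjustment over the genes tested, and a gene was called at an adjusted p under 0.05. The comparisons were tunicamycin against control at 2 h, the same at 8 h, the difference between these effects, and control at 8 h against control at 2 h. The 2 tunicamycin comparisons share no library. The log2 fold changes at both times were also correlated across genes, as a description without a p-value.

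An exact 0 in such a table can be a failed estimate. Of the genes tested, 587 were listed at 0 in at least 1 library and at 10 FPKM or more in another. They were kept in the tests. Ranges of fold changes in the report leave them out, a choice made after the values were seen, and no fold is given for a group listed at 0.

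The absolute depth of the libraries is unknown. The relative value of 1 fragment in each library was taken from genes under 1 FPKM in every library. It was the most common ratio of their values to those in control 2 h replicate 1. This assumes that the most common ratio comes from genes with the same number of fragments in both libraries. By this measure the shallowest library, control 2 h replicate 2, had 70.5% of the depth of the deepest, tunicamycin 2 h replicate 3. This depth is in fragments per unit of FPKM, so it follows the scaling of the deposited values and is not the total of fragments. Whole fragments could not be recovered per gene, since only 57.2% of 49621 ratios between low values and the smallest value of their gene came within 0.03 of a whole number. Low genes therefore carry a counting error that cannot be given.

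The test was checked on simulated values drawn around the real mean and residual spread of the 12056 genes, with 200 genes changed. For the 2 h comparison, 75% of the genes changed by 1 on the log2 scale and 91% of those changed by 2 were recovered, with 5 false calls among 171. For the 8 h comparison, these shares were 76% and 90%, with 9 false calls among 175. The simulated values were independent between genes, and each gene had the same spread in every library. The check therefore does not cover genes that move together, a library that stands apart or differences between experiments.

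Alternatives fixed before the data were examined were a pseudocount of 0.1 or 5, no filter on low values or a mean of at least 5 FPKM, median-ratio scaling, quantile normalization, a fit on only the groups compared, no trend, limma array weights, the replicate number as a block, each library left out, and for counts of genes a 2-fold minimum or an adjusted p under 0.01. Single libraries were left out only from the groups of the comparison in question. Added after seeing the data were a fit without the genes listed at 0 and, for the 2 h comparison, a fit without control 8 h replicate 2. The ordering of genes by their control 2 h level, with and without that library, was also added then. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.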

Results

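RNA was profiled in cultured oligodendrocyte precursor cells, the dividing progenitors of the myelin-forming cells of the central nervous system. The cells were taken from adult rat spinal cord. Tunicamycin blocks the N-linked glycosylation of proteins in the endoplasmic reticulum and is used to induce endoplasmic reticulum stress. Cells received 5 µM tunicamycin or none for 2 or 8 h, and both times precede cell death per the study's design. Each of the 4 groups held 3 libraries, and the 12 libraries came from 3 independent experiments. The purpose stated by the study was to find parts of the transcriptional stress response that bear on whether these cells survive.

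Between 11360 and 12224 genes reached 1 FPKM in a library. Summed FPKM ran from 588250 to 764988, and relative depth, in fragments per unit of FPKM, varied by up to 1.42-fold between libraries. The first principal component of log2(FPKM + 1) held 27.5% of the variance. The 3 libraries at 8 h of tunicamycin scored 45.6, 52.7 and 52.8 on it, and the other 9 scored from −27.9 to 1.01. The second component held 19.6% of the variance and was led by 1 library, control 8 h replicate 2, at −79.3. That library had the lowest summed FPKM, with the next lowest at 690766, and the most genes at 1 FPKM, with the next highest at 11600. Its rank correlation across genes with the other libraries ran from 0.867 to 0.908, whereas all pairs without it ran from 0.906 to 0.973.

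**Figure D1:**
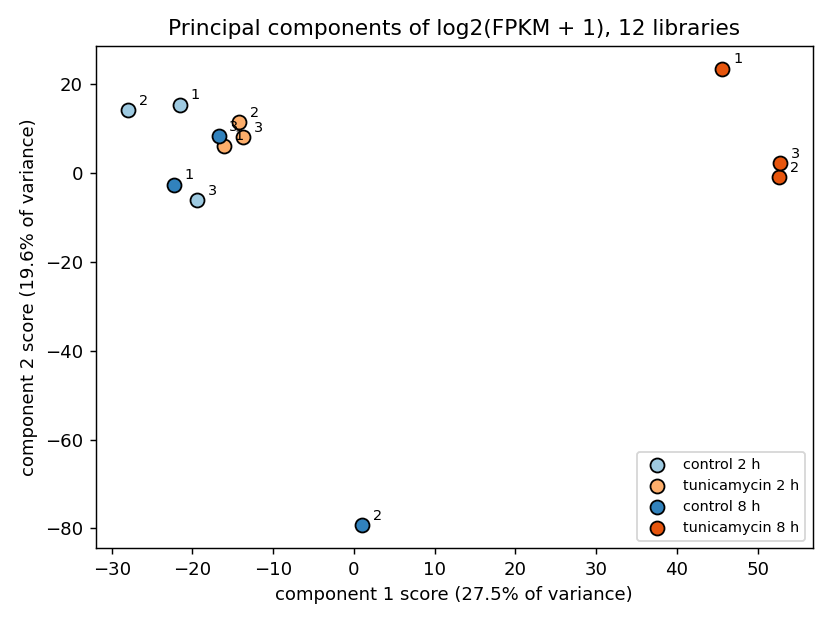
Scores of the 12 libraries on the first 2 principal components of log2(FPKM + 1), with the share of variance of each on its axis; colours give the group and numbers the replicate. The 3 libraries at 8 h of tunicamycin score 45.6 to 52.8 on component 1, and control 8 h replicate 2 scores −79.3 on component 2.

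The first comparison asked what tunicamycin changed within 2 h. The early response was small and mostly upward: 60 genes rose and 7 fell among 12056 tested (limma, adjusted p under 0.05). The genes that rose had a median log2 fold change of 0.76, and 21 of them rose at least 2-fold. The gene ENSRNOG00000006789 went from 43.2 ± 5.27 FPKM in control to 142 ± 16.0 FPKM with tunicamycin (mean ± SD, n = 3 each), a log2 fold change of 1.69 ± 0.10 (SE; limma adjusted p = 0.000201). ENSRNOG00000007319 went from 5.71 ± 1.74 to 14.2 ± 1.15 FPKM, a log2 fold change of 1.21 ± 0.17 (SE; limma adjusted p = 0.0179). Its call was lost when only the 2 h libraries were fitted (limma adjusted p = 0.143, the highest over its alternatives, which reached down to 0.000122), and when control 2 h replicate 1 or any 1 of the 3 treated libraries at 2 h was left out.

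Of the 10 largest rises at 2 h, 1 was a gene listed at 0 in the control libraries. The other 9 had log2 fold changes from 1.18 to 2.19. Only 7 genes fell, short of the 10 that were to be described, and 1 of these is among the genes listed at 0. The other 6 had log2 fold changes from −0.41 to −0.81. All 67 called genes had treated and control libraries that did not overlap, as had 18.2% of all genes tested, where chance gives 10% for 3 against 3 libraries. The count depended on single libraries: leaving out control 2 h replicate 1, 2 or 3 gave 18, 18 and 35 genes, and leaving out tunicamycin 2 h replicate 1, 2 or 3 gave 19, 21 and 23. Without control 8 h replicate 2, which only adds to the spread shared by the fit, 114 genes were called. The count was 30 with only the 2 h libraries fitted, 32 with the replicate number as a block and 40 after quantile normalization. It was 1428 with limma array weights, where 788 were higher and 640 lower, a far more even balance. That fit leaned on 1 library outside this comparison, tunicamycin 8 h replicate 3, with a weight of 103.

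The second comparison asked what tunicamycin had changed by 8 h. The response was now broad and in both directions, with 2142 genes higher and 1874 lower, or 33.3% of the genes tested (limma, adjusted p under 0.05). Most changes were moderate. The median log2 fold change was 0.62 among genes that rose and −0.66 among genes that fell, and 445 rose and 381 fell at least 2-fold. Large changes were more often rises: without the genes listed at 0, 76 rose and 30 fell at least 4-fold, and 14 rose and 3 fell at least 8-fold. The genes that rose, again without those listed at 0, held 11.6% ± 1.10 of the summed FPKM of the tested genes in control at 8 h and 20.04% ± 0.300 with tunicamycin (SD, n = 3 each). The genes that fell went from 11.9% ± 0.499 to 6.59% ± 0.101 (SD, n = 3 each). These shares describe genes picked by the same comparison. In the 2 h libraries, whose levels do not enter the 8 h fold changes although their spread enters the test, the genes that rose held 11.3% ± 0.235 in control and 12.8% ± 0.418 with tunicamycin, and the genes that fell held 12.3% ± 0.869 and 11.8% ± 0.200 (SD, n = 3 each).

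The largest rise at 8 h among genes not listed at 0 was that of ENSRNOG00000007319, from 7.76 ± 0.809 FPKM in control to 190 ± 23.2 FPKM with tunicamycin (mean ± SD, n = 3 each), a log2 fold change of 4.45 ± 0.17 (SE; limma adjusted p = 1.02e-07). The next was ENSRNOG00000006789, from 42.9 ± 1.74 to 711 ± 10.5 FPKM, a log2 fold change of 4.02 ± 0.10 (SE; limma adjusted p = 1.48e-08). Of the 10 largest rises, 3 were genes listed at 0 in some library, and the other 7 had log2 fold changes from 3.66 to 4.45. The largest fall among genes not listed at 0 was that of ENSRNOG00000009550, from 175 ± 5.90 to 17.8 ± 2.03 FPKM, a log2 fold change of −3.23 ± 0.08 (SE; limma adjusted p = 1.48e-08). At 2 h this gene stood at 194 ± 9.61 FPKM in control and 205 ± 6.08 FPKM with tunicamycin (log2 fold change 0.08, limma adjusted p = 0.984). Of the 10 largest falls, 5 were genes listed at 0 in some library, and the other 5 had log2 fold changes from −2.93 to −3.23. The rest of the 10 includes ENSRNOG00000018294, which lay between 784 and 1376 FPKM in the 9 other libraries and was listed at 0 in all 3 libraries at 8 h of tunicamycin. These zeros may be failed estimates, so whether this gene fell, rose or stayed level at 8 h is not known.

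**Figure D2:**
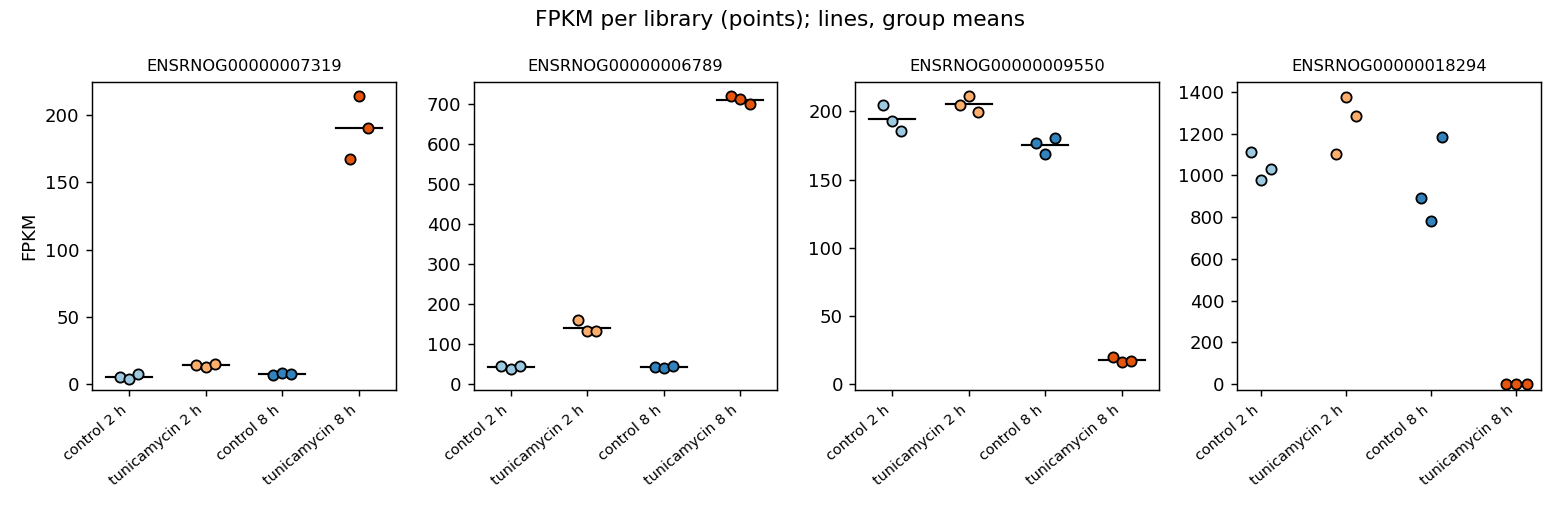
FPKM of 4 genes in each of the 12 libraries (points) by group, with the group means as lines for the 3 genes that are not listed at 0 anywhere. ENSRNOG00000007319 and ENSRNOG00000006789 reach means of 190 and 711 FPKM at 8 h of tunicamycin, ENSRNOG00000009550 drops to 17.8 FPKM, and ENSRNOG00000018294 is listed at 0 in those 3 libraries and at 784 to 1376 FPKM in the others.

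Above 1 FPKM, the balance of rises and falls over expression level depended on 1 library. Genes not listed at 0 were ordered by their mean in control at 2 h, which does not enter the 8 h fold changes but adds to the spread used in the test. Of the called genes, 90.9% were higher among the 302 genes under 1 FPKM, which reach the mean of 1 FPKM required over the 12 libraries only through other groups. The share was 47.3% among the 2555 genes of 1 to 5 FPKM, and 56.1% among the 1182 genes of at least 100 FPKM. Control 8 h replicate 2, in which 832 genes lay at least 2-fold above the mean of the other 2 libraries of its group, is 1 of the 3 controls. Without it the last 2 shares were 54.4% and 33.1%, so their order turned, and the share under 1 FPKM was 96.9%. In the whole table, 16 genes stayed under 0.5 FPKM in all 6 control libraries and were at 2 FPKM or more in all 3 libraries at 8 h of tunicamycin, up to a mean of 14.4 FPKM, and 11 of them were also under 0.5 FPKM in all libraries at 2 h of tunicamycin. The reverse, at 2 FPKM or more in all 6 controls and under 0.5 FPKM in the 3 treated libraries, held for 1 gene, ENSRNOG00000018294. Its 3 treated values are exact zeros, which may be failed estimates. These counts have a background without treatment. Between 2 groups of 3 libraries, 20 genes met the limits upward at 8 h of tunicamycin against control at 8 h and 9 at 2 h, and 12 did so in control at 8 h against control at 2 h. No test was made of these counts.

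Of the genes called at 8 h, 2102 of those higher and 1802 of those lower had treated and control libraries that did not overlap. Over all genes tested this held for 41.2%, against 10% by chance. The 8 h count was 2591 with only the 8 h libraries fitted. Leaving out single libraries at 8 h gave counts from 3044 to 5042, the highest without control 8 h replicate 2.

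The third comparison asked whether the effect of tunicamycin differed between 2 and 8 h. It differed for 1595 genes, 901 with a higher and 694 with a lower log2 fold change at 8 h (limma interaction, adjusted p under 0.05). Of these, 900 were called higher and 673 called lower at 8 h in the same direction as the difference. Without control 8 h replicate 2, the count was 2657, and with array weights 2944.

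Most genes called at 2 h were also called in the same direction at 8 h. Among the 59 genes that rose at 2 h and were not listed at 0, 48 were also called higher at 8 h, and 37 had a larger point estimate of the log2 fold change at 8 h. The median over the 59 was 0.73 at 2 h and 0.92 at 8 h. The difference itself was called upward in 24 of the 59 genes and downward in 10. Both named genes that rose belong to the 24: the difference between the times was 3.23 ± 0.24 for ENSRNOG00000007319 (SE; limma adjusted p = 2.66e-05) and 2.33 ± 0.15 for ENSRNOG00000006789 (SE; limma adjusted p = 1.05e-05). The largest early rise did not grow in this way, with a log2 fold change of 2.19 at 2 h and 2.29 at 8 h. All 6 genes that fell at 2 h and were not listed at 0 were also called lower at 8 h. For comparison, lists of these sizes drawn independently from the 11469 genes not listed at 0 would share 10.95 genes called higher at both times and 0.974 called lower. Both lists rest on the same spread per gene, which favours genes of low spread in both, so these values are not what the overlap would be without a shared effect.

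A smaller part of the early response had ended or turned. Of the 59 genes that rose at 2 h and were not listed at 0, 7 were not called at 8 h and 4 were called lower at 8 h. The difference between the times was called for all 4 that turned and for 6 of the 7 that were not called. For the 4, opposite calls in the same fit bring this almost by construction. The median log2 fold change of the 4 was 1.06 at 2 h and −1.13 at 8 h. The late response was larger than both: 2093 genes were called higher and 1864 lower at 8 h without a call at 2 h, and 12 and 13 of them are listed at 0. The difference between the times was called for 875 of the 2093 and 666 of the 1864. Across all 12056 genes the log2 fold changes at 2 h and 8 h had a Pearson correlation of 0.15 and a Spearman correlation of 0.41. Genes are not independent replicates, and the 2 comparisons share no library. The Pearson correlation was 0.32 without the genes listed at 0, 0.069 with a pseudocount of 0.1 and 0.23 with a pseudocount of 5.

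**Figure D3:**
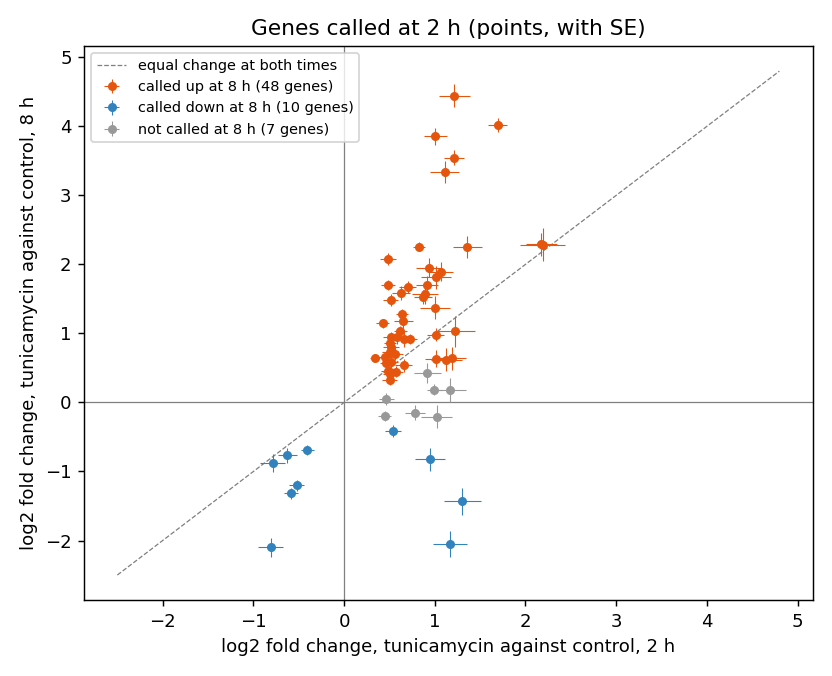
Log2 fold changes of tunicamycin against control at 2 h (horizontal) and 8 h (vertical) for the 65 genes called at 2 h that are not listed at 0; bars are standard errors and the dashed line marks equal change. Of the 59 genes that rose at 2 h, 37 lie above the line, and 4 lie well below 0 on the vertical axis and were called lower at 8 h.

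The last comparison gives the background of time in culture, control at 8 h against control at 2 h. It called 3 genes, 2 higher and 1 lower, and 384 genes had an unadjusted limma p under 0.05 where 603 would by chance. All 3 are listed at 0 in every library of 1 of the 2 groups, and none is named for that reason. Without the genes listed at 0, limma called 0 genes, and 348 of 11469 had an unadjusted p under 0.05. The count was 6 without control 8 h replicate 1 or 2, 9 without replicate 3, 1 with a pseudocount of 5 and 5 with array weights. ENSRNOG00000006789 stood at 43.2 and 42.9 FPKM in the controls at 2 and 8 h, and ENSRNOG00000007319 at 5.71 and 7.76 FPKM (log2 difference 0.41, limma adjusted p = 0.66).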

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

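The tests of single libraries and of the gene listed at 0 were chosen after the results were seen; the regroupings of libraries were chosen before.

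The effect of tunicamycin differed between 8 h and 2 h for 1595 genes by the interaction test, and 5 genes were called in opposite directions at the 2 times. Of the 5, 4 rose at 2 h and were lower at 8 h, and the interaction was called for all 5, with the largest adjusted p at 0.000769 (limma). Opposite calls in the same fit bring a called interaction almost by construction, so this adds no support. The fifth is listed at 0 in all 3 control libraries at 8 h, and its direction there rests on those zeros.

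When the times were reassigned within the control and within the treated libraries, 7 of 100 assignments, the real one included, gave at least 1595 genes, and the highest other gave 2346. All 7 kept the treated libraries in their own times. Of the 200 possible assignments, 20 do so, which leaves too little room for a share under 0.05, so this count decides nothing on chance. Among the 93 that regrouped treated libraries the highest count was 5. For the single times, 10 splits of 6 libraries are too few for a share under 0.05. At 2 h the real split gave 67 genes, the only 1 of the 10 to reach that number, and the highest other gave 3. At 8 h the real split gave 4016, again 1 of 10, and the highest other 190. For control at 8 h against 2 h, 5 of the 10 splits gave at least the 3 genes of the real one, and the highest other gave 4.

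Control 8 h replicate 2 stands apart, with 832 genes at least 2-fold above the mean of the other 2 libraries of its group, where the other 11 libraries have 45 to 154. A treated library under a control label is argued against: the 103 genes at least 4-fold higher at 8 h of tunicamycin than in control at 2 h lay a median of 0.22 above the other 2 control 8 h libraries on the log2 scale (interquartile range 0 to 0.54), against a median rise of 2.42. Lower depth is argued against only in the sense of fewer fragments per unit of FPKM, since 2 other libraries have a larger value of 1 fragment without such an excess. These are control 2 h replicate 2 and tunicamycin 8 h replicate 1, with 77 and 90 genes at least 2-fold above the mean of their group's other libraries. A smaller total of fragments stays open, since the totals are unknown and this library had the lowest summed FPKM, 588250. A fault of this 1 library alone stays open: its 175 genes at least 4-fold above both other control 8 h libraries have medians from 1.74 to 2.45 in the 3 libraries at 8 h of tunicamycin, a gap of 0.70, where the gaps in the other groups, leaving this library out, are 0.07 to 0.17, but 3 libraries per group do not decide. RNA of another cell type may also contribute and was not tested, since the genes carry no names. A difference between the experiments was not tested either. Over the 175 genes, the log2 medians in replicate 2 at 2 h were 1.63 in control and 1.70 with tunicamycin. The other libraries at 2 h had 1.66 to 1.79. At 8 h of tunicamycin, replicate 2 had 2.39, between replicates 1 and 3. The libraries numbered 2 thus show no common excess, but no source says that a number marks an experiment.

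ENSRNOG00000018294 is listed at 0 in all 3 libraries at 8 h of tunicamycin and lies at 784 FPKM or more in the other 9. If the zeros are true levels, a loss of its RNA no faster than that of any other abundant gene is argued against. Of 873 genes at 100 FPKM or more in every control 8 h library, it is the only one at 0. The next lowest kept 10.2% of its control level, which would leave 97.0 of its 953 FPKM. The gene was picked for its zeros, so its lowest rank was fixed in advance, and only the gap to the next gene was not. A failed estimate in the quantification remains a candidate explanation and cannot be told apart from an exceptional loss here. Under a failed estimate, neither its level at 8 h of tunicamycin nor the direction of its change is known. At 2 h it was listed at 1104 to 1376 FPKM with tunicamycin and at 979 to 1113 FPKM in control. Zeros do occur where treatment cannot be the cause, in 17 library values whose other 2 libraries of the group hold at least 50 FPKM, but none of those 15 features was at 0 in a single library and as even as this gene elsewhere; among genes at 10 FPKM or more in all libraries of the other groups, 1 other is at 0 in a whole group, control at 8 h, and lies between 29.2 and 82.8 FPKM in the other 9 libraries, which goes with a failed estimate at a much lower level, and without that limit the other 2 genes called between the control times are at 0 in all 3 control libraries at 2 h as well.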

How the results depend on the processing

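All alternatives below were fixed before the data were examined, except the fits without genes listed at 0 and, for 2 h, without control 8 h replicate 2. Causes of the changes were not tested, except where fewer genes or libraries or a stricter threshold act by construction.

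The number of genes called at 2 h, 67, became 40 after quantile normalization, 30 with only the groups compared, 1428 with array weights, 22 at 2-fold or more and 15 at an adjusted p under 0.01. Without single libraries it ran from 18 to 114, the highest without control 8 h replicate 2. The 8 h count, 4016, became 2591 with only the groups compared, 826 at 2-fold or more and 2576 at an adjusted p under 0.01. It ran from 3044 to 5042 when single libraries at 8 h were left out. The count for the difference between the times, 1595, became 2944 with array weights, 545 at 2-fold or more and 746 at an adjusted p under 0.01. Without single libraries it ran from 1069 to 2657, the highest without control 8 h replicate 2. The 3 genes of control at 8 h against 2 h became 1 with a pseudocount of 5, 5 with array weights and 0 without the genes listed at 0 (348 at an unadjusted limma p under 0.05). Without single libraries they ran from 3 to 9, with 6 without control 8 h replicate 1 or 2 and 9 without replicate 3. The array weights ranged from 0.0691 for control 8 h replicate 2 to 103 for tunicamycin 8 h replicate 3, so that fit leaned on 1 library. The Pearson correlation of the log2 fold changes, 0.15, became 0.069 with a pseudocount of 0.1, 0.23 with a pseudocount of 5 and 0.32 without the genes listed at 0, and ran from 0.10 to 0.17 without single libraries. Apart from the replicate block at 2 h, given in the next paragraph, the other alternatives kept these counts within 1.5 times. Where it was computed, they kept the correlation within its jackknife standard error of 0.07. The correlation has no value with array weights, without the trend or with only the groups compared. The difference between the times has no count with only the groups compared. Median-ratio scaling gave 66, 3993 and 1591 genes for the first 3 comparisons. Its factors ran only from 0.996 to 1.01, so it could change little and does not show that the counts are robust to the scaling.

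Replicate numbers were not shown to pair the libraries, since no source used here says that a number marks an experiment. The sample numbers in the column names run in sets of 4 by replicate number, the size of the stated experiments. A pairing therefore stays possible, and the low correlations given next do not exclude it. Deviations from the group means of libraries with the same number had correlations from −0.18 to 0.13, and 2 of the 12 libraries correlated best with their own number. The replicate block gave 32, 3717, 1253 and 2 genes for the 4 comparisons and left the correlation at 0.15.

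For the 3 genes with tests that are named, 94 of 99 log2 fold changes under the alternatives kept their direction and side of the threshold, and 0 reversed. The 5 that lost the call all concern ENSRNOG00000007319 at 2 h. Tests of gene lists (camera with preset and estimated correlation, and fry) were not run, since the gene IDs have no names here. Absolute depth is unknown, which leaves the counting error of low genes unmeasured.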

Other observations

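The test of the lean at 2 h was chosen before its result was seen, the counts in this part after.

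As a set, genes called at 8 h already leaned the same way at 2 h, although few were called there. Among the 2129 genes higher at 8 h and not listed at 0, 78.0% had a log2 fold change above 0 at 2 h, with a median of 0.10, and 48 were called higher at 2 h. Among the 1861 genes lower at 8 h, 21.2% were above 0 at 2 h, with a median of −0.11, and 6 were called lower and 4 higher. Of the 30 at least 4-fold lower at 8 h, 36.7% were above 0 at 2 h, with a median of 0. In this set, 1 gene was called in each direction at 2 h. With this share above 0, a median of 0 means that some of the 30 had a log2 fold change of 0. Such genes lean neither way, so the set does not show the lean and is weak evidence against it. Of the 76 at least 4-fold higher, 73.7% were above 0. Among the 7479 genes not called at 8 h, 43.3% were above 0.

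A hypothesis is that the 8 h response had begun by 2 h across many genes below the reach of a test on single genes. The real split of the 2 h libraries gave the same sign as at 8 h for 78.3% of 3990 genes, the only 1 of the 10 splits to reach that share (the 8 h response had begun at 2 h), but the highest other split gave 75.1%. Genes that move together are not independent, so a high share can arise from 1 shared axis among libraries, and 10 splits are too few for a share under 0.05. The lean may be an early response or such an axis, and these libraries cannot tell the 2 apart.

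In control 8 h replicate 2, genes at least 2-fold above the mean of the other 2 libraries of the group were a larger share at low expression, with levels taken from control at 2 h and genes listed at 0 left out. They were 14.7% of the 2555 genes of 1 to 5 FPKM and 0.846% of the 1182 genes of at least 100 FPKM. In the other 5 libraries at 8 h, these shares were at most 1.60% and 0.931%. Its 175 genes at least 4-fold above both other libraries of its group, chosen for that excess, had a median of 12.9 FPKM in it and of 1.67 and 1.55 FPKM in control 8 h replicates 1 and 3. Their medians were 2.34, 4.26 and 4.45 FPKM in tunicamycin 8 h replicates 1, 2 and 3. Only 8 genes lay at least 4-fold below both other libraries. At high expression there was an excess downward as well. Of the 1182 genes of at least 100 FPKM, 3.98% lay at least 2-fold below the mean of the other 2 libraries. This share was at most 0.423% in the other 5 libraries at 8 h.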
